A study of Mus musculus with 57 samples.

How the data were processed

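The series holds 57 Affymetrix Mouse Gene 1.0 ST arrays in 19 groups. The unit of each deposited value is a linear probe set intensity: per the submitters' processing notes the arrays were summarized with RMA in Affymetrix Expression Console 1.3.1. The plan assumed RMA values on the log2 scale, and since the intensities ran from 7.16 to 19571, their log2 was taken before any test. Median intensities lay between 105.8 and 128.4 in the 51 TRAP arrays and between 43.9 and 53.3 in the 6 total RNA arrays. The total RNA arrays thus appear to have been normalized apart, and no level was compared across both kinds except in the alternatives that say so.

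Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 none in the platform table. Probe sets with exactly 1 symbol were kept (19938 genes), and for 999 genes with more than 1 probe set the one with the highest mean over the arrays of the fit was used. Genes with a log2 value above 5 in at least 3 arrays were tested, 19244 in the fit of 45 arrays and 19302 in the fit of 57 arrays. Symbols of the platform were matched to a mouse gene table by gene identifier (21698 matched). Of 532 list entries 489 were matched to a measured gene.

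One linear model with 1 coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). The fit of 45 arrays in 15 groups left out the 12 background arrays and had 30 residual degrees of freedom, a prior of 3.06 and a median residual SD of 0.153 on the log2 scale. The fit of all 57 arrays (38 residual degrees of freedom, prior 3.18, median residual SD 0.154) served the comparisons that need background arrays. P values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at adjusted p under 0.05. Differences among the 4 IRI responses were tested with a moderated F test and as the response of each line minus the mean response of the other 3. Age differed between some groups and could not be separated from them, so it was no covariate. Errors are standard errors from the limma fit, with the prior included.

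The comparisons, the test, the gene lists, the rule for named genes and most alternatives were set before the data were examined, except the adipocyte and small nucleolar RNA sets and the alternatives named as added later. Named genes were the 8 highest and 8 lowest by log2 fold change in each IRI comparison at 24 h, and the 5 highest and 5 lowest in each other comparison, among called genes whose arrays were fully separated (no such separation was asked of response differences). Up to 4 called members of each list with the largest change were added, and a fixed panel of injury and cell type genes of which 15 were measured. Predicted genes known only by a clone or number were left out. In the response differences and in comparisons between lines, the text names some of these genes and not all. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and the genes shown there were chosen after the results were seen.

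The 27 gene lists were written from general knowledge of the kidney. The 10 of cell types covered proximal tubule, thick ascending limb and distal tubule, collecting duct, podocyte, endothelial, interstitial with pericyte and mesangial, macrophage with monocyte and dendritic cell, neutrophil, lymphocyte and erythroid genes. The 17 of responses covered tubular injury, immediate early and AP-1, heat shock, unfolded protein and ATF4, NRF2 targets, p53 targets, hypoxia and glycolysis, cytokines with chemokines and NF-kB, interferon response, cell cycle, extracellular matrix, complement and coagulation, endothelial activation, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis and circadian clock. Members that passed were counted over all genes and adjusted over the list alone. Lists were tested with camera of limma with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists of a comparison. A list of adipocyte genes and the set of small nucleolar RNAs were added after results were seen and were only counted.

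Genes shared between comparisons are given with the number expected if calls were independent, which they are not where comparisons share arrays. For the 4 h and 24 h responses, which share sham arrays, data without any change were simulated with the observed spread. Regrouping the arrays gave counts of calls for groupings other than the real one: all 10 splits of 3 against 3 arrays, all 35 of 4 against 4, and 100 random ones elsewhere.

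The analysis was tested on simulated data in which 50 genes at each of 4 fold changes were changed. In the nephron IRI comparison 78 percent of genes changed 1.5-fold, 88 percent of those changed 2-fold and 100 percent of those changed 4-fold were recovered, and for the F test 40, 80 and 100 percent. False calls made up 1.90 to 6.70 percent of the calls. The simulated noise was independent and normal with the same spread in every group, as the model assumes. These shares therefore do not cover groups that vary unequally. A shifted set of 30 genes was found by camera in each of 4 simulated comparisons and a random set in 0.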

Results

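The series measured which messenger RNAs were attached to tagged ribosomes in 4 kidney cell populations of the mouse, before and after the renal blood supply was stopped for 28 min and restored. Translating ribosome affinity purification (TRAP) pulls down ribosomes that carry a tagged L10a protein. Cre recombinase lines placed the tag in nephron epithelium (Six2-Cre), interstitial cells (Foxd1-Cre), endothelial cells (Cdh5-Cre) or myeloid cells (Lyz2-Cre). Each line had 3 arrays from kidneys taken 24 h after ischemia-reperfusion injury (IRI), 3 from sham surgery and 3 from mice without surgery. The nephron line had 3 more arrays 4 h after IRI. A pair of background sets carried the purification through kidneys without Cre: mice with the L10a allele (4 IRI and 2 sham arrays) and wild-type mice (4 IRI and 2 sham arrays). The labels of the L10a arrays give the genotype both as homozygous and as heterozygous, and describe these arrays as background from podocytes and some collecting duct cells. Whole-kidney total RNA completed the series with 3 IRI and 3 sham arrays. This gives 57 arrays in 19 groups, all from male mice. With 3 arrays in most groups, the number of animals limits the precision of every value. The labels call the arrays biological replicates without saying more. Sham surgery at 24 h served as control for the 4 h arrays, since no sham at 4 h was analysed here. The ages in the labels also differed: nephron sham and IRI mice were 8 weeks old and those without surgery 6, and myeloid IRI mice were 9.5 and their controls 7 weeks old. All interstitial and endothelial mice were 6 weeks old.

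Changes are given as log2 fold changes with their standard error (SE) and the adjusted p of limma over 19244 genes (19302 where background arrays entered). A gene is said to rise or fall where that adjusted p was under 0.05. For each gene named as among the highest or lowest between 2 groups, all arrays of 1 group lay on the same side of all arrays of the other. Gene lists were tested with camera, once with a preset correlation between genes and once with a correlation estimated from the data. Scaling the arrays again by quantile normalization turned the direction of 0 named results that were called before or after it.

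In mice without surgery the 4 lines were compared with each other, each against the mean of the other 3. Nephron arrays held less of the macrophage gene Ly86 (-6.00 ± 0.21, adjusted p = 4.7e-22), of Kdr, the vascular growth factor receptor of endothelium (-3.58 ± 0.16), and of Pdgfrb of pericytes (-2.22 ± 0.24). They held more Angptl7 (4.01 ± 0.45) and Slc22a30 (2.38 ± 0.40), but both turned direction with total RNA as the reference, an alternative added after seeing the data that compares sham arrays (-1.22, adjusted p = 0.0522 and -0.57, adjusted p = 0.362, so neither opposite change passed). Proximal tubule markers were higher in 24 of 29 (25 adjusted over the list alone) and 0 were lower. Camera gave them adjusted p = 1.0e-04, but adjusted p = 0.45 with an estimated correlation. All 25 measured endothelial markers were lower in the nephron line, among them Emcn (-4.24 ± 0.20). So were 25 of 26 markers of macrophages, monocytes and dendritic cells (adjusted p = 0.0066 with an estimated correlation for both lists). Interstitial arrays carried more Penk (4.98 ± 0.19, adjusted p = 1.1e-20), Pdgfrb (3.02 ± 0.24), Des of contractile filaments (3.88 ± 0.26) and Col1a1 of fibrillar collagen (2.72 ± 0.14). In this line 22 of 23 interstitial, pericyte and mesangial markers were higher (22 adjusted over the list alone, camera adjusted p = 2.4e-30). Fat cell genes came with them: Cox8b was higher by log2 5.24 ± 0.48, Retn by 4.74 ± 0.37 and Cidec by 4.59 ± 0.44. With that same reference Cox8b (1.11, adjusted p = 0.115) and Retn (0.40, adjusted p = 0.479) did not pass. Of 18 measured adipocyte genes 12 were higher. Endothelial arrays held more Esm1 (4.49 ± 0.15, adjusted p = 9.9e-23), Kdr (3.72 ± 0.16), Tek (3.85 ± 0.25) and Gimap6 (4.11 ± 0.13). There all 25 measured endothelial markers were higher (25 adjusted over the list alone). Macrophage markers went with them in 25 of 26, lymphocyte markers in 13 of 14 and interferon response genes in 15 of 16 (adjusted p = 0.095 with an estimated correlation for lymphocyte markers). Blood cell messages in the endothelial arrays included Lyz2 (2.50 ± 0.30) and Cd3g (2.41 ± 0.13). Myeloid arrays held more of the nucleic acid sensors Tlr8 (4.47 ± 0.21, adjusted p = 1.4e-18) and Tlr7 (4.19 ± 0.18), of C3ar1 (3.83 ± 0.25) and of Adgre1, the F4/80 antigen of macrophages (3.39 ± 0.21). In this line 25 of 26 macrophage, monocyte and dendritic cell markers were higher (25 adjusted over the list alone). Collecting duct water channel Aqp2 (1.47 ± 0.22) and 8 of 12 podocyte markers were also higher in the myeloid line, among them Ptpro (1.55 ± 0.19). Podocytes and some collecting duct cells are also what the labels give as the source of the L10a background without Cre. The podocyte list had camera adjusted p = 0.0016, and adjusted p = 0.34 with an estimated correlation. By limma, 9867 genes differed between the nephron line and the others, 6286 for the interstitial, 7917 for the endothelial and 7264 for the myeloid line. When the 12 arrays were regrouped, 2 of 100 groupings, the real one included, gave as many calls for the interstitial and for the myeloid line (at most 6583 and 8880 in another grouping).

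The background arrays show which messages came through the purification without Cre. All TRAP arrays have similar median intensities, so levels compare composition and not amounts of RNA. In wild-type kidneys after IRI, compared with sham (4 against 2 arrays), Krt20, a keratin of stressed epithelium, rose by log2 6.49 ± 0.39, adjusted p = 6.1e-17, the iron-binding protein gene Lcn2 by 5.36 ± 0.46, the shed kidney injury marker Havcr1 by 4.63 ± 0.74 and Hmox1, which breaks down heme, by 3.42 ± 0.21. The transporters Slco4c1 (-4.97 ± 0.43) and Slc7a12 (-4.22 ± 0.56) and the cholesterol synthesis gene Cyp51 (-2.33 ± 0.35) fell. Of 21 tubular injury genes 19 rose (20 adjusted over the list alone, camera adjusted p = 1.5e-11, and adjusted p = 0.058 with an estimated correlation). Small nucleolar RNAs were higher in 24 of 47 and lower in 0 in the same comparison. Also higher were 19 of 20 immediate early and AP-1 genes, such as Fosl1 (3.66 ± 0.23) and Myc (3.30 ± 0.21), with adjusted p = 0.058 with an estimated correlation. In kidneys with the L10a allele, Sprr2f of the epithelial barrier rose by 5.68 ± 0.53, Krt20 by 5.66 ± 0.39 and the repair factor Sox9 by 2.80 ± 0.29. Ranbp3l (-5.38 ± 0.34), the vasopressin receptor Avpr2 (-4.09 ± 0.27) and the potassium channel Kcnj1 (-3.59 ± 0.38) fell there. By limma 7321 of 19302 genes were called in wild-type and 7419 in L10a background arrays (4944 without L10a sham replicate 1). After IRI the 2 backgrounds differed in 8962 genes: L10a arrays held more of the podocyte regulator Wt1 (2.78 ± 0.17, adjusted p = 2.4e-17), of Fxyd4 (3.41 ± 0.19) and Aqp2 (2.29 ± 0.22) of the collecting duct and of Foxd1 (2.72 ± 0.12). They held less Apob (-3.82 ± 0.34), Cubn (-2.77 ± 0.28) and Tnc (-2.60 ± 0.38). All 29 measured proximal tubule markers were lower in L10a arrays and 11 of 12 podocyte markers were higher (adjusted p = 0.25 with an estimated correlation for both lists). For tubular injury genes and a few others, the level in background arrays is given beside the change in a Cre line below.

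**Figure D1:**
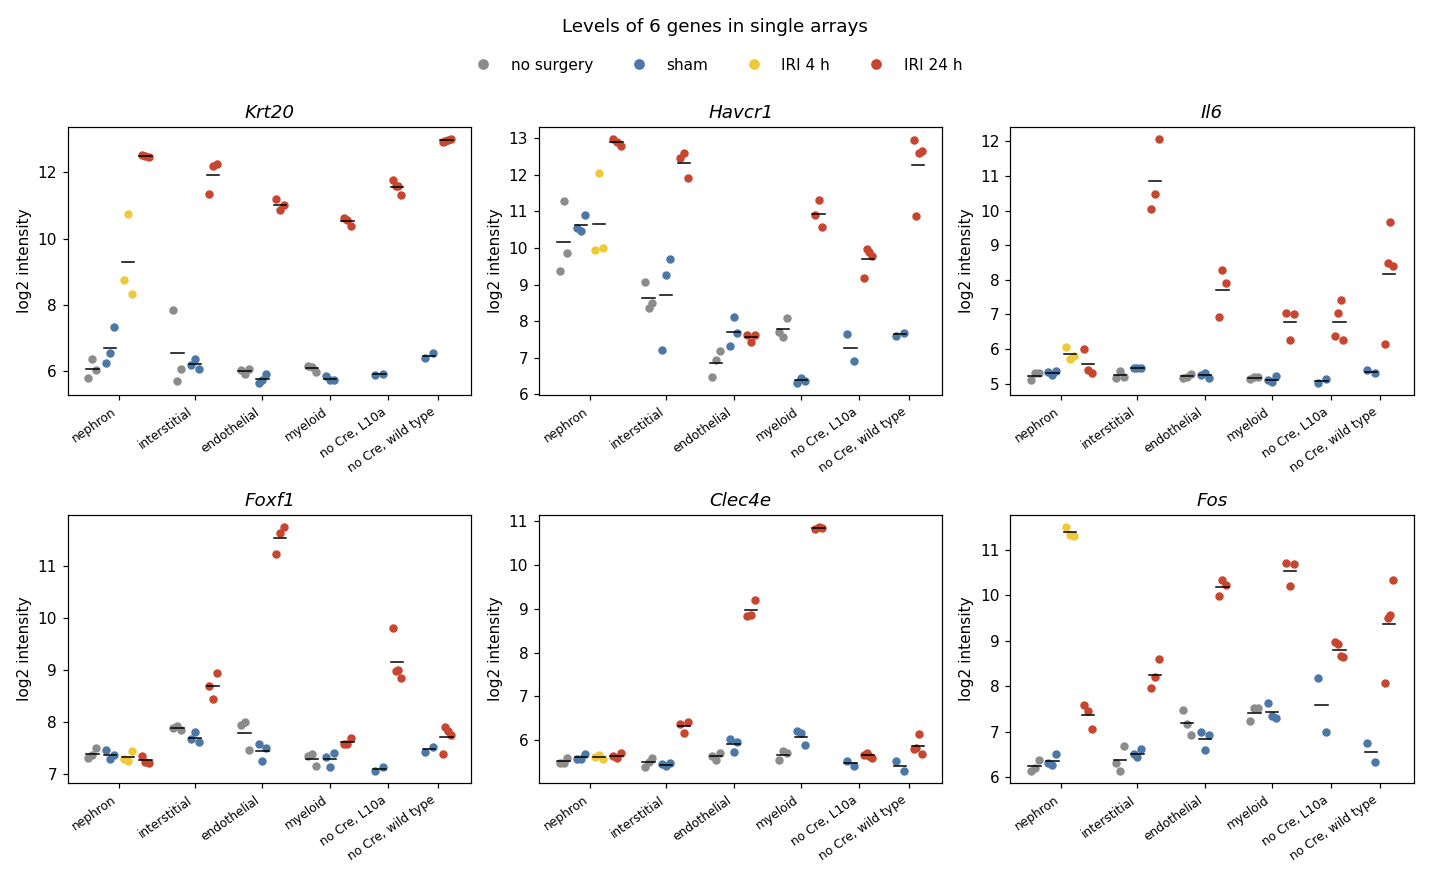
Log2 intensity of 6 genes in single TRAP arrays (points) with group means (lines), for the 4 lines and both background sets without Cre. Krt20 rose in every set, Havcr1 did not rise in endothelial arrays, Il6 was highest in interstitial, Foxf1 in endothelial and Clec4e in myeloid arrays after IRI, and Fos was highest in nephron arrays at 4 h.

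How did nephron epithelium respond 24 h after IRI? Krt20 had the largest rise of the named genes, log2 5.78 ± 0.41, adjusted p = 1.1e-12, followed by the fibrinogen chain Fgb (4.83 ± 0.51, adjusted p = 4.9e-09) and the barrier genes Sprr2f (4.21 ± 0.41) and Sprr2g (3.96 ± 0.32). Next came the urokinase receptor Plaur (3.83 ± 0.22), the AP-1 subunit Fosl1 (3.80 ± 0.22), Akr1b8 (3.76 ± 0.28) and the cystine importer Slc7a11 (3.68 ± 0.26). The largest falls were those of Ceacam2 (-3.75 ± 0.53), Akr1c14 (-3.64 ± 0.44), Tmem207 (-3.31 ± 0.17, adjusted p = 5.6e-16), the brush border protease Mep1b (-3.31 ± 0.35) and Acmsd of tryptophan breakdown (-3.24 ± 0.41). Among the known injury genes Sox9 rose by 3.35 ± 0.24, adjusted p = 2.5e-12, Lcn2 by 2.47 ± 0.48, adjusted p = 1.3e-04 and Havcr1 by 2.26 ± 0.74, adjusted p = 0.019. Havcr1 did not pass without IRI replicate 1 (2.21), sham replicate 1 (2.21) or sham replicate 2 (2.17), though the change itself hardly moved. Its nephron arrays were fully separated, with log2 intensities of 12.80 to 12.98 after IRI and 10.47 to 10.90 in sham. The SE of 0.74 pools the spread of Havcr1 over all groups of the fit. Among these are the total RNA arrays after IRI, where it ran from 7.73 to 12.58. By limma 5503 of 19244 genes were called (2669 higher and 2834 lower), 565 of them at least 2-fold higher and 675 at least 2-fold lower.

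Of 21 tubular injury genes 20 rose in nephron arrays (21 adjusted over the list alone, camera adjusted p = 7.5e-23). Of 20 immediate early and AP-1 genes 18 rose (18 adjusted over the list alone), such as Atf3 (2.42 ± 0.22). Stress programs moved with them: 9 of 14 NRF2 targets rose (9 adjusted over the list alone), 9 of 13 p53 targets (9), among them Btg2 (1.91 ± 0.15) and Eda2r (1.27 ± 0.16). Of 18 genes of the unfolded protein and ATF4 response 11 rose (12), among them Asns, which makes asparagine (2.19 ± 0.39), and Chac1 (2.05 ± 0.25). Of 15 complement and coagulation genes 9 rose (9 adjusted over the list alone), with Plat, the tissue plasminogen activator, at 2.88 ± 0.27 and Fgg at 2.77 ± 0.66. These 6 lists also passed camera with an estimated correlation, with adjusted p from 0.0076 for tubular injury to 0.048 for complement and coagulation. Markers of the thick ascending limb and distal tubule fell in 9 of 14 (9 adjusted over the list alone, adjusted p = 0.043 with an estimated correlation). The salt transporter Slc12a1 (-2.69 ± 0.31), Pvalb (-2.39 ± 0.27) and Ppp1r1a (-1.92 ± 0.15) led them. Proximal tubule markers fell in 16 of 29 (16 adjusted over the list alone), among them G6pc of glucose release (-2.49 ± 0.44) and the amino acid carrier Slc7a13 (-2.45 ± 0.34). The phosphate carrier Slc34a1 did not pass (-0.13 ± 0.15, adjusted p = 0.56). Camera gave that list adjusted p = 8.4e-05, and adjusted p = 0.47 with an estimated correlation.

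Cholesterol synthesis fell in 8 of 14 genes (9 adjusted over the list alone), with Idi1 at -1.78 ± 0.31, and oxidative phosphorylation in 10 of 23 (11 adjusted over the list alone). With camera these gave adjusted p = 8.7e-05 and 0.0013, but adjusted p = 0.12 and 0.26 with an estimated correlation. Cytokine, chemokine and NF-kB genes rose in 12 of 24 (14 adjusted over the list alone), led by the neutrophil attractant Cxcl2 (2.70 ± 0.41) and the feedback inhibitor Socs3 (2.48 ± 0.23). The 2 probe sets of Socs3 disagreed, with the other at 0.378. Extracellular matrix genes rose in 10 of 21 (10), led by Ccn2 (2.99 ± 0.20) and the protease inhibitor Timp1 (2.92 ± 0.35). Both lists had adjusted p = 0.11 with an estimated correlation. Macrophage markers were mixed in nephron arrays: 8 of 26 rose, among them Cd68 (3.27 ± 0.28) and Cd14 (3.08 ± 0.33), and 1 fell, Csf1r, the receptor that maintains macrophages (-1.13 ± 0.17). Camera gave the list adjusted p = 0.002, and adjusted p = 0.47 with an estimated correlation. Weaker or mixed lists in nephron arrays were the cell cycle (7 of 27 higher), heat shock (6 of 14 higher and 1 lower), endothelial markers (7 of 25 higher and 1 lower) and neutrophil genes (3 of 16 higher, 1 adjusted over the list alone). Their camera calls were lost, with adjusted p = 0.49, 0.26, 0.52 and 0.47 with an estimated correlation. Camera made no call for fatty acid oxidation (6 of 19 lower, 1 higher), collecting duct (5 of 16 lower, 1 higher), podocyte (4 of 12 lower, 1 higher) and circadian clock genes (8 of 16 lower, 3 higher). Nor was one made for interferon response (2 of 16 higher, 1 lower), endothelial activation (2 of 15 higher, 1 lower), interstitial (2 of 23 higher), lymphocyte (1 of 14 higher) and erythroid genes (1 of 4 lower). Their camera adjusted p lay between 0.12 and 0.82. Hypoxia and glycolysis genes rose in 6 and fell in 5 of 19, with a median of -0.14, a mean of 0.12 and an upward camera result (adjusted p = 0.31). Krt20 reached a mean log2 intensity of 12.49 in nephron and 12.96 in wild-type background arrays after IRI. Of the 20 tubular injury genes that rose, 13 lay above the background. When only genes above the wild-type background were tested, 3503 genes were called in nephron arrays. Levels after IRI were compared for genes higher after IRI, and sham levels for genes lower, so the choice used the observed direction.

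The nephron line also had arrays 4 h after IRI. The AP-1 genes Fosb (5.39 ± 0.32) and Fos (5.02 ± 0.21, adjusted p = 2.4e-18) had the largest rises of the named genes, followed by the stress factor Atf3 (4.66 ± 0.22, adjusted p = 8.1e-17), Ifrd1 (3.79 ± 0.36) and Nr4a1 (3.62 ± 0.40). The heat shock gene Hspa1a rose by 3.23 ± 0.36. Ceacam2 (-2.91 ± 0.53), Psca (-2.36 ± 0.32) and Apoc3 (-2.01 ± 0.26) fell. Of the injury markers, Havcr1 (0.03 ± 0.74, adjusted p = 0.99) and Lcn2 (-0.38 ± 0.48, adjusted p = 0.67) did not pass at 4 h, while Krt20 was higher by 2.57 ± 0.41 and Sox9 by 1.77 ± 0.24. Krt20 rested partly on replicate 2 (log2 intensity 10.75, with 8.74 and 8.34 in the others). Of 20 immediate early genes 19 rose (19 adjusted over the list alone), and of 14 heat shock genes 10 (12), such as Dnajb1 (2.53 ± 0.29). Of 18 unfolded protein and ATF4 genes 9 rose (13), such as Ddit3, which promotes cell death under stress (1.90 ± 0.16). Cytokine genes rose in 13 of 24 (14 adjusted over the list alone), led by Socs3 (2.52 ± 0.23, but 0.702 in its other probe set). Tubular injury genes rose in 12 of 21 (12), led by Ccn1 (3.39 ± 0.33), and hypoxia and glycolysis genes in 9 of 19 with 2 lower. All 6 lists passed camera with an estimated correlation (adjusted p from 4.3e-04 to 0.042). Of the p53 targets 6 of 13 rose (6 adjusted over the list alone), with Plk2 at 2.80 ± 0.24 and the death gene Pmaip1 at 2.44 ± 0.16 (adjusted p = 0.062 with an estimated correlation). Of 29 proximal tubule markers 0 were lower at 4 h and 1 was higher, and of the thick ascending limb markers 1 was lower and 2 were higher. By limma 3492 genes were called at 4 h (1450 higher, 2042 lower), or 5557 in a fit of the 2 groups alone.

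From 4 h to 24 h, Fgb rose by 4.71 ± 0.51, adjusted p = 9.9e-09, Slc7a11 by 3.71 ± 0.26, Mlkl, which ruptures membranes in necroptosis, by 3.53 ± 0.24, adjusted p = 1.0e-12, Serpina3n by 3.51 ± 0.52, Lcn2 by 2.85 ± 0.48 and Havcr1 by 2.23 ± 0.74, adjusted p = 0.02. Fosb (-4.18 ± 0.32), Fos (-4.01 ± 0.21), Akr1c14 (-3.75 ± 0.44) and Acmsd (-3.46 ± 0.41) fell. Thick ascending limb and distal tubule markers fell in 12 of 14 (12 adjusted over the list alone, adjusted p = 0.0099 with an estimated correlation), with Slc12a1 at -3.16 ± 0.31 and the growth factor Egf at -2.50 ± 0.51. Proximal tubule markers fell in 15 of 29 (20 adjusted over the list alone), heat shock genes in 10 of 14, immediate early genes in 14 of 20 and oxidative phosphorylation genes in 14 of 23 (17 adjusted over the list alone). For these 4 lists adjusted p = 0.3, 0.15, 0.15 and 0.14 with an estimated correlation. Havcr1 did not pass without 24 h replicate 1 (2.19), 4 h replicate 1 (1.87) or 4 h replicate 3 (1.90). By limma 5335 genes differed between the time points. Of the genes called at 4 h, 787 were higher and 855 lower at both times against the shared sham arrays (201 and 301 expected by chance). Against the arrays without surgery instead at 4 h, 790 and 715 were shared. Across all genes the 2 responses correlated with r = 0.451, near the 0.499 that shared sham arrays alone gave in simulated data, but with a larger covariance (0.0892 against 0.0129). They correlated with r = 0.416 with the arrays without surgery as control at 4 h.

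How did interstitial cells respond? The cytokine Il6 rose by log2 5.41 ± 0.32, adjusted p = 1.3e-14, the chemokine Cxcl2 by 5.58 ± 0.41, adjusted p = 1.4e-12, Pi15 by 5.16 ± 0.31 and Timp1 by 4.43 ± 0.35. Fosl1 rose by 4.09 ± 0.22, Plaur by 4.00 ± 0.22 and the epithelial gene Krt20 by 5.71 ± 0.41. Ceacam2 (-4.20 ± 0.53), Mep1b (-3.73 ± 0.35), Akr1c14 (-3.62 ± 0.44), Slc22a19 (-3.58 ± 0.40) and Rasgef1b (-3.40 ± 0.21) fell. The marker Pdgfrb of the line itself did not pass (0.22 ± 0.29, adjusted p = 0.57). The integrin Itga8 fell (-1.67 ± 0.17) and the contractile gene Tagln rose (1.31 ± 0.18). Interstitial markers were higher in 3 and lower in 9 of 23 (camera adjusted p = 0.19). By limma 7579 genes were called (3721 higher, 3858 lower).

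Neutrophil genes rose in 14 of 16 in interstitial arrays (14 adjusted over the list alone, adjusted p = 0.033 with an estimated correlation), among them Retnlg (3.63 ± 0.35), S100a9 (2.98 ± 0.34) and the decoy receptor Il1r2 (2.94 ± 0.19). Cytokine, chemokine and NF-kB genes rose in 18 of 24 (19 adjusted over the list alone), led by Cxcl1 (3.83 ± 0.27) and Lif (3.42 ± 0.33). Extracellular matrix genes rose in 13 of 21 with 2 lower, led by Tnc (3.11 ± 0.41), Vcan (2.26 ± 0.22) and Thbs1 (2.00 ± 0.18). Endothelial activation genes rose in 9 of 15, such as Ch25h (3.03 ± 0.26) and Procr, a receptor for protein C (2.44 ± 0.18). For these 3 lists adjusted p = 0.12, 0.23 and 0.18 with an estimated correlation. Macrophage markers fell in 15 of 26 (17 adjusted over the list alone), such as Adgre1 (-1.64 ± 0.26) and Lyz2 (-1.66 ± 0.36), while 5 rose, among them Itgam (1.83 ± 0.25) and Cd14 (1.68 ± 0.33). Interferon response genes fell in 8 of 16, and for the 2 lists adjusted p = 0.53 and 0.35 with an estimated correlation. Fatty acid oxidation fell in 18 of 19 genes (19 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation), among them Acadm (-1.81 ± 0.18) and Decr1 (-1.70 ± 0.19). The sham arrays it is measured from themselves held more of 9 of these genes than arrays without surgery, and 13 of 47 small nucleolar RNAs rose after IRI. Oxidative phosphorylation fell in 18 of 23 (19), with adjusted p = 0.12 with an estimated correlation.

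Tubular messages moved in the same interstitial arrays. All 21 measured tubular injury genes rose (adjusted p = 0.033 with an estimated correlation), among them Havcr1 (3.60 ± 0.74), Lcn2 (3.85 ± 0.48) and Sox9 (2.45 ± 0.24). Of 29 proximal tubule markers 25 fell (26 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). The backgrounds after IRI disagreed on how far these genes came through without the tag: Havcr1 averaged 12.32 in interstitial, 12.27 in wild-type and 9.71 in L10a background arrays. Over the 21 injury genes the interstitial level minus the wild-type background level had a median of -0.118 (SE 0.212, 10 of 21 above), and minus the L10a level one of 0.472 (SE 0.321, 13 of 21 above). Il6 in contrast averaged 10.86 in interstitial with 8.18 in wild-type and 6.78 in L10a background arrays. When only genes above the wild-type background were tested, 4403 genes were called.

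How did endothelial cells respond? Foxf1, a transcription factor of vessels and mesenchyme, rose by log2 4.10 ± 0.15, adjusted p = 2.2e-20, the activin subunit Inhbb by 3.99 ± 0.22 and Krt20 by 5.25 ± 0.41. Vessel activation showed in Edn1, which encodes a constrictor (2.94 ± 0.29), the adhesion gene Sele (2.25 ± 0.14) and Apln (2.13 ± 0.23). Single endothelial genes fell, Tek, the angiopoietin receptor, at -1.77 ± 0.31, the transcription factors Erg at -1.42 ± 0.11 and Sox18 at -1.36 ± 0.18, and Icam2 at -1.07 ± 0.10. As a list these markers did not move together: Kdr did not pass (-0.13 ± 0.20, adjusted p = 0.62), and 4 of 25 endothelial markers rose against 7 that fell (camera adjusted p = 0.058). Of 15 endothelial activation genes 10 rose (11 adjusted over the list alone, camera adjusted p = 0.0021, and adjusted p = 0.26 with an estimated correlation). The peptide gene Apela fell (-3.47 ± 0.42). By limma 8309 genes were called (4131 higher, 4178 lower), the largest count of the 4 lines. Small nucleolar RNAs were higher in 8 of 47 and lower in 0.

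Blood cell messages also changed in the endothelial arrays. The neutrophil genes Ngp (4.47 ± 0.36), Cxcr2 (4.26 ± 0.29), Il1r2 (4.26 ± 0.19, adjusted p = 3.3e-18) and Clec4d (4.05 ± 0.19) rose with all 16 measured neutrophil markers (16 adjusted over the list alone, adjusted p = 0.0037 with an estimated correlation). Monocyte and macrophage genes fell, with the chemokine receptors Ccr2 at -3.68 ± 0.22 and Cx3cr1 at -3.67 ± 0.23 and the leukotriene receptor Cysltr1 at -3.89 ± 0.26. So did 13 of 26 macrophage markers (14 adjusted over the list alone) and 8 of 14 lymphocyte markers, such as Nkg7 of killer cells (-2.23 ± 0.22) and Cd3g (-1.89 ± 0.16). Of 16 interferon response genes 7 fell, such as Oas1a (-1.72 ± 0.11). For these 3 lists adjusted p = 0.34, 0.38 and 0.39 with an estimated correlation. Stress programs included 19 of 20 immediate early genes, with Fos at 3.34 ± 0.21 and Fosb at 3.45 ± 0.32, and 9 of 14 heat shock genes (10 adjusted over the list alone), with Hspa1a at 3.18 ± 0.36 and Hspb8 at 1.58 ± 0.23. Cytokine genes rose in 16 of 24 (17), with Cxcl2 at 4.34 ± 0.41 and the monocyte attractant Ccl2 at 3.09 ± 0.27. The 3 lists had adjusted p = 0.26, 0.34 and 0.31 with an estimated correlation. The clock genes Nfil3 (3.49 ± 0.26), Cry1 (1.86 ± 0.24) and Per1 (1.56 ± 0.27) rose and Dbp fell (-1.56 ± 0.22), with 9 of 16 clock genes higher (camera adjusted p = 0.064). Fatty acid oxidation fell in 14 of 19 genes (adjusted p = 0.38 with an estimated correlation). Tubular injury genes rose in 16 of 21 (16 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation) but Havcr1 did not pass (-0.15 ± 0.74, adjusted p = 0.88). For the 16 that rose, the level minus that of the wild-type background had a median of -0.652 (SE 0.212, 4 of 16 above).

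How did myeloid cells respond? The lectin receptor Clec4e rose by log2 4.75 ± 0.10, adjusted p = 2.8e-28, the amplifier of inflammation Trem1 by 5.02 ± 0.12, adjusted p = 1.2e-26, the collagenase Mmp8 by 5.03 ± 0.21, adjusted p = 1.5e-19, Slc7a11 by 5.05 ± 0.26, adjusted p = 1.0e-16, the chemokine receptor Cxcr2 by 4.85 ± 0.29 and Clec4d by 4.80 ± 0.19. Falling genes were Xcr1, which marks a dendritic cell subset (-3.58 ± 0.14), the chemokine Ccl12 (-3.55 ± 0.14), Gpr141b (-3.83 ± 0.18), Cx3cr1 of resident macrophages (-2.93 ± 0.23) and Aif1 (-1.62 ± 0.26). Arg1, which consumes arginine, rose by 3.57 ± 0.14, adjusted p = 2.7e-20 and Itgam by 1.43 ± 0.25. Neutrophil genes rose in 15 of 16 (15 adjusted over the list alone, adjusted p = 8.7e-05 with an estimated correlation), while macrophage markers moved both ways (4 higher and 4 lower of 26, camera adjusted p = 0.98). In this as in the other lines, a change in which cells were present and a change within the cells cannot be told apart. Myeloid IRI mice were also older than their sham controls (9.5 against 7 weeks), so age cannot be told apart from IRI either. Lyz2, the gene whose promoter drove Cre in this line, did not pass (-0.61 ± 0.36, adjusted p = 0.23), but passed with array weights (-0.72, adjusted p = 0.0103) and in a fit of the 2 groups alone (adjusted p = 0.00309). By limma 5378 genes were called (2525 higher, 2853 lower), or 9669 with array weights.

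Interferon response genes fell in 12 of 16 in myeloid arrays (13 adjusted over the list alone), among them Usp18 (-2.07 ± 0.20) and Ifit3 (-1.93 ± 0.32). Extracellular matrix genes rose in 12 of 21, among them Timp1 (3.21 ± 0.35), Tnc (3.07 ± 0.41), Vcan (2.99 ± 0.22) and Thbs1 (2.94 ± 0.18). Both lists had adjusted p = 0.13 with an estimated correlation. Immediate early genes rose in 12 of 20 (14 adjusted over the list alone), with Fos at 3.11 ± 0.21, but Atf3 did not pass (-0.36 ± 0.22, adjusted p = 0.25). Of the cytokine genes 13 of 24 rose and 2 fell, and of the NRF2 targets 7 of 14 rose and 2 fell (adjusted p = 0.19, 0.21 and 0.1 with an estimated correlation for the 3 lists). Tubular messages moved here too. All 21 measured tubular injury genes rose, with Sprr2f at 5.29 ± 0.41 and Havcr1 at 4.55 ± 0.74, and 11 of 14 markers of the thick ascending limb and distal tubule fell (adjusted p = 0.029 with an estimated correlation for both lists). Collecting duct markers fell in 12 of 16, such as Hsd11b2 (-2.96 ± 0.35) and Avpr2 (-2.58 ± 0.27), and proximal tubule markers in 22 of 29 (24 adjusted over the list alone). Collecting duct and proximal tubule had adjusted p = 0.056 and 0.13 with an estimated correlation. For the 21 injury genes the level minus that of the wild-type background had a median of -0.871 (SE 0.269, 5 of 21 above), with Havcr1 at 10.93 against 12.27 there and 9.71 in the L10a background. Of the myeloid genes 3539 were called among those above that background.

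**Figure D2:**
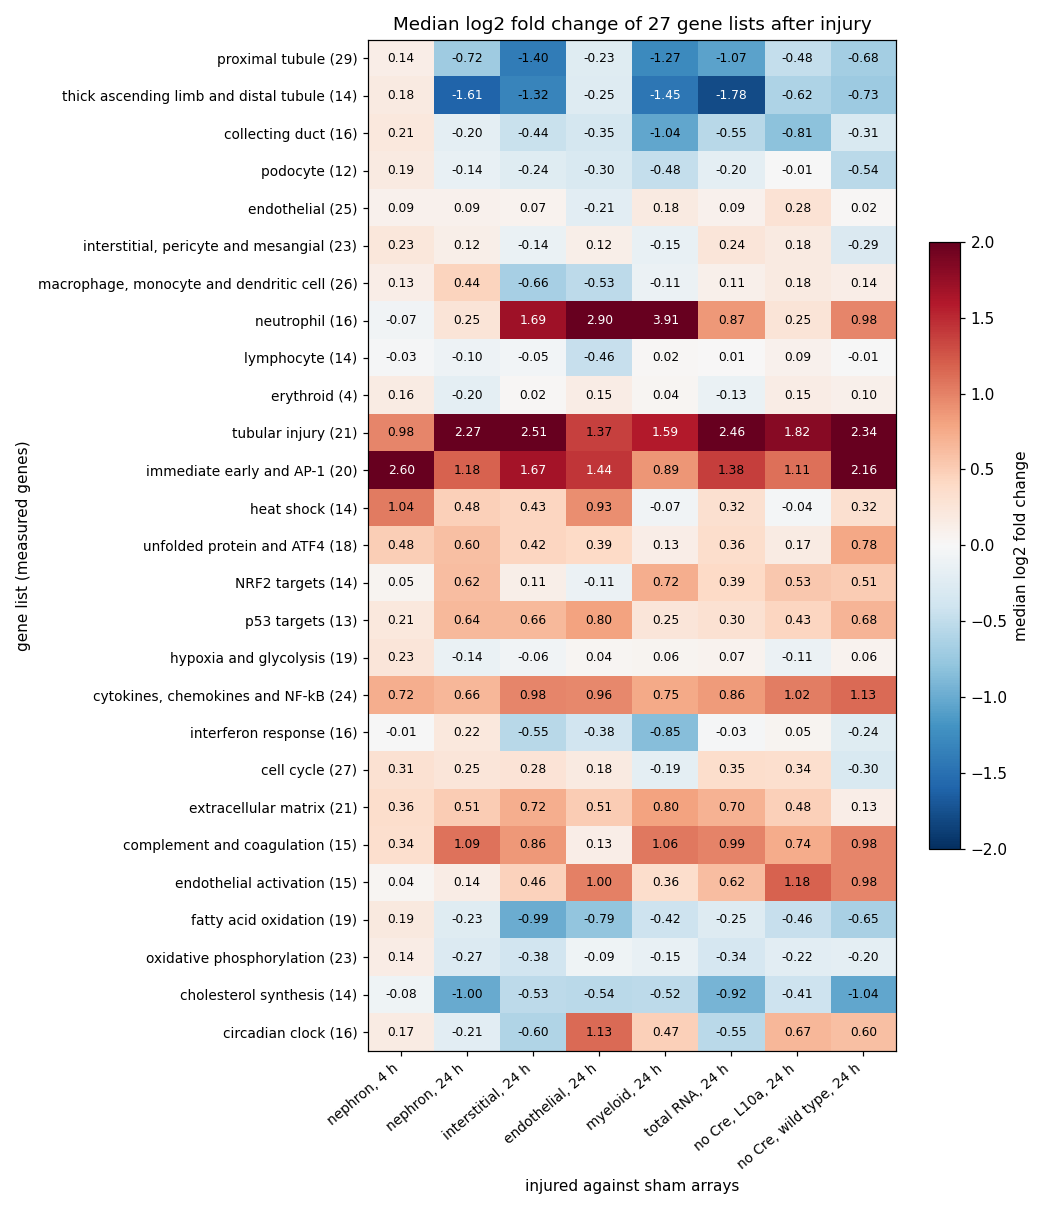
Median log2 fold change against sham of 27 gene lists (lines of the map) in 8 comparisons (columns), red for higher and blue for lower. Neutrophil genes had medians of 2.90 in endothelial and 3.91 in myeloid but 0.25 in nephron arrays, and tubular injury genes were higher in each of the 8 columns.

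How far did the 4 responses overlap, and where did they differ? At 24 h 623 genes were higher and 700 lower in all 4 lines (14.5 and 18.3 expected if the lines were independent). Of the 13214 genes called in at least 1 line, 1158 rose in 1 line and fell in another. By correlation the responses of nephron and interstitial arrays were the closest of the lines (r = 0.703). They shared 1685 genes higher and 1897 lower (516 and 568 expected). Interstitial and endothelial arrays shared the most genes (2015 higher and 2112 lower in both, 799 and 838 expected, r = 0.588). Nephron and endothelial responses were the furthest apart by correlation (r = 0.369, 1277 and 1213 shared, 573 and 615 expected). Nephron and myeloid arrays shared the fewest genes (1048 and 1162, 350 and 420 expected, r = 0.498). Lines with more calls share more genes by number alone, so the shared counts do not rank how alike the responses were. The wild-type background response correlated with that of interstitial arrays by r = 0.745 (2176 genes higher and 2231 lower in both), with nephron by 0.603, endothelial by 0.534 and myeloid arrays by 0.478. A moderated F test found responses that differed among the lines for 8975 genes. Each line was then compared with the mean response of the other 3. A higher response there means a higher log2 fold change, which a smaller fall also gives.

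The nephron response was larger for Cd68 (3.71 ± 0.33, adjusted p = 3.7e-10), Layn (3.63 ± 0.35), Fgb (2.90 ± 0.59) and Sox9 (1.08 ± 0.28). It was smaller for Il1r2 (-3.55 ± 0.22, adjusted p = 1.1e-13), Trem1 (-3.24 ± 0.14), Il6 (-2.92 ± 0.37) and Fos (-1.72 ± 0.24). Neutrophil genes had a smaller response there in 15 of 16 (15 adjusted over the list alone, adjusted p = 6.0e-04 with an estimated correlation). The log2 fold change of macrophage markers was higher there than in the other lines in 18 of 26 and of interferon response genes in 9 of 16 (adjusted p = 0.39 and 0.38 with an estimated correlation). Falls elsewhere contributed: 15 of 26 macrophage markers fell in interstitial and 13 in endothelial arrays, and 8, 7 and 12 of 16 interferon response genes fell in interstitial, endothelial and myeloid arrays. In interstitial arrays the response exceeded the others for Il6 (3.95 ± 0.37, adjusted p = 2.0e-09), Pi15 (3.84 ± 0.36), Cxcl5, which attracts neutrophils (3.37 ± 0.30), the cytokine Il11 (3.07 ± 0.32) and Tnfsf18 (3.71 ± 0.31). It lay below them for Ifitm1 (-3.48 ± 0.17, adjusted p = 3.7e-16), Rasgef1b (-3.27 ± 0.24) and the hormone Epo, which drives red cell formation (-2.65 ± 0.27). Fatty acid oxidation genes fell further there than in the mean of the others in 12 of 19 (15 adjusted over the list alone, adjusted p = 0.43 with an estimated correlation). In endothelial arrays the response was higher for Foxf1 (3.69 ± 0.18, adjusted p = 7.2e-17), Inhbb (3.17 ± 0.25), Sele (2.02 ± 0.16), the vessel destabilizer Angpt2 (1.87 ± 0.23) and Slc12a1 (2.88 ± 0.35). Lower there was the response of Havcr1 (-3.62 ± 0.85, adjusted p = 0.0014), Fgb (-3.34 ± 0.59), Ccr2 (-3.22 ± 0.25) and Erg (-1.27 ± 0.13). Endothelial markers responded lower in 10 of 25, clock genes higher in 11 of 16 and neutrophil genes higher in 11 of 16 (adjusted p = 0.44, 0.34 and 0.32 with an estimated correlation). Myeloid arrays led for the chitinase-like gene Chil3 (4.00 ± 0.12, adjusted p = 1.4e-22), Clec4e (3.43 ± 0.11), Mmp8 (3.31 ± 0.24), Arg1 (3.29 ± 0.16) and Trem1 (3.14 ± 0.14). Their response was lower for Ch25h (-3.11 ± 0.30), Ccl12 (-2.84 ± 0.16), Myc (-2.79 ± 0.23) and Atf3 (-2.62 ± 0.25, adjusted p = 2.1e-09). Neutrophil genes responded more there in 11 of 16 (adjusted p = 0.0034 with an estimated correlation) and immediate early genes less in 11 of 20 (adjusted p = 0.61 with an estimated correlation). The counts were 4477 for nephron, 3064 for interstitial, 5583 for endothelial and 3555 for myeloid arrays, with 1, 7, 4 and 2 of 100 groupings as large, the real one included. Real IRI effects stay in those groupings, so they are no test without change.

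Whole-kidney total RNA arrays had lower median intensities than the TRAP arrays (43.9 to 53.3 against 105.8 to 128.4) and were tested only within themselves. Krt20 rose by log2 6.44 ± 0.41, adjusted p = 1.4e-13, Havcr1 by 4.39 ± 0.74, adjusted p = 2.0e-05, Lcn2 by 4.25 ± 0.48 and Fgb by 4.21 ± 0.51. Fgg rose by 4.20 ± 0.66, the growth regulator Myc by 3.56 ± 0.20 and the TWEAK receptor Tnfrsf12a by 3.29 ± 0.23. In a fit of the total RNA arrays alone Havcr1 (adjusted p = 0.127), Fgb (0.0863) and Fgg (0.0918) did not pass. Ceacam2 (-4.49 ± 0.53), the steroid enzymes Akr1c18 (-4.39 ± 0.39) and Cyp7b1 (-3.98 ± 0.38) and Acmsd (-3.72 ± 0.41) fell. Thick ascending limb and distal tubule markers fell in 13 of 14 (14 adjusted over the list alone) and collecting duct markers in 9 of 16 (10). Cholesterol synthesis genes fell in 11 of 14 (11) and oxidative phosphorylation genes in 15 of 23 (15). Tubular injury genes rose in 20 of 21 (20) and immediate early genes in 18 of 20 (18). These 6 lists passed camera with an estimated correlation (adjusted p from 0.0016 to 0.04). Neutrophil genes rose in 12 of 16, extracellular matrix genes in 14 of 21 and cell cycle genes in 11 of 27 (13 adjusted over the list alone), with adjusted p = 0.084, 0.094 and 0.42 with an estimated correlation. Small nucleolar RNAs were higher in 12 of 47 and lower in 0. By limma 5958 genes were called with the variance of all 45 arrays and 689 in a fit of the total RNA arrays alone. IRI replicate 3 stood apart from replicates 1 and 2 (5321 calls without it in the larger fit). It also had the highest median intensity of the total RNA arrays (53.3). Havcr1 was 7.73 in it against 12.0 and 12.6, and Fgb 6.58 against 10.5 and 10.7, so their means mix unlike arrays.

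What did surgery without ischemia change? Sham was compared with no surgery in each line. The interstitial line had the most calls, but this order is not firm: with only the arrays compared, nephron arrays had 973 calls, interstitial 350, endothelial 20 and myeloid arrays 26, and with array weights myeloid arrays had 3076 and interstitial arrays 3034. Nephron sham mice were 8 and nephron mice without surgery 6 weeks old, so age and surgery cannot be told apart in that line. In nephron arrays (311 genes) Slco4c1 was higher by 2.67 ± 0.38, and Ptpn22 (-2.57 ± 0.23, adjusted p = 8.9e-09) and the clock gene Arntl (-1.86 ± 0.25, adjusted p = 3.1e-05) were lower. So were 5 of 27 cell cycle genes (11 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation). Endothelial arrays (142 genes) held less Top2a, which untangles DNA in dividing cells (-1.31 ± 0.19, adjusted p = 9.4e-05), though its other probe set hardly differed (-0.0285). There 13 of 27 cell cycle genes were lower (24 adjusted over the list alone, adjusted p = 5.3e-04 with an estimated correlation). Myeloid arrays (323 genes) held more of the alarmins S100a8 (2.55 ± 0.33, adjusted p = 3.2e-05) and S100a9 (2.49 ± 0.34), with 5 of 16 neutrophil genes higher (9 adjusted over the list alone). Proximal tubule markers were lower in 12 of 29 in the myeloid arrays (23 adjusted over the list alone), among them the endocytosis receptor Cubn (-1.37 ± 0.34), and both lists passed with an estimated correlation (adjusted p = 0.035 and 0.032). Cubn did not pass without myeloid no surgery replicate 1 (-1.31) or 3 (-1.28), or without sham replicate 1 (-0.86) or 3 (-1.41). In interstitial arrays (1985 genes) the fat metabolism gene Thrsp (-2.90 ± 0.32, adjusted p = 1.3e-06), Retn (-2.25 ± 0.45) and Adipoq (-2.22 ± 0.43) were lower. The lipid enzyme Cyp4a14 (3.51 ± 0.78) and Ptprb of endothelium (1.28 ± 0.26) were higher. In fits of the 2 groups alone Cyp4a14 (adjusted p = 0.0558), Ptprb (0.0909), Retn (0.0528), in endothelial arrays Top2a (0.111) and in myeloid arrays Cubn (0.141) did not pass. The 26 myeloid calls of that fit were 19 higher and 7 lower, so the 12 lower proximal tubule markers were not all called in it. Fatty acid oxidation genes were higher there in 9 of 19 (14 adjusted over the list alone) and endothelial markers in 7 of 25 (10), both with adjusted p = 0.74 with an estimated correlation. In the same interstitial arrays 10 of 18 adipocyte genes were lower and 15 of 47 small nucleolar RNAs higher. These counts depended on single arrays more than the others: without interstitial sham replicate 3 the interstitial count was 809, and without myeloid no surgery replicate 3 the myeloid count was 35 (550 without myeloid sham replicate 2). Without endothelial sham replicate 2 the endothelial count was 55, and without nephron no surgery replicate 1 the nephron count was 105.

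**Figure D3:**
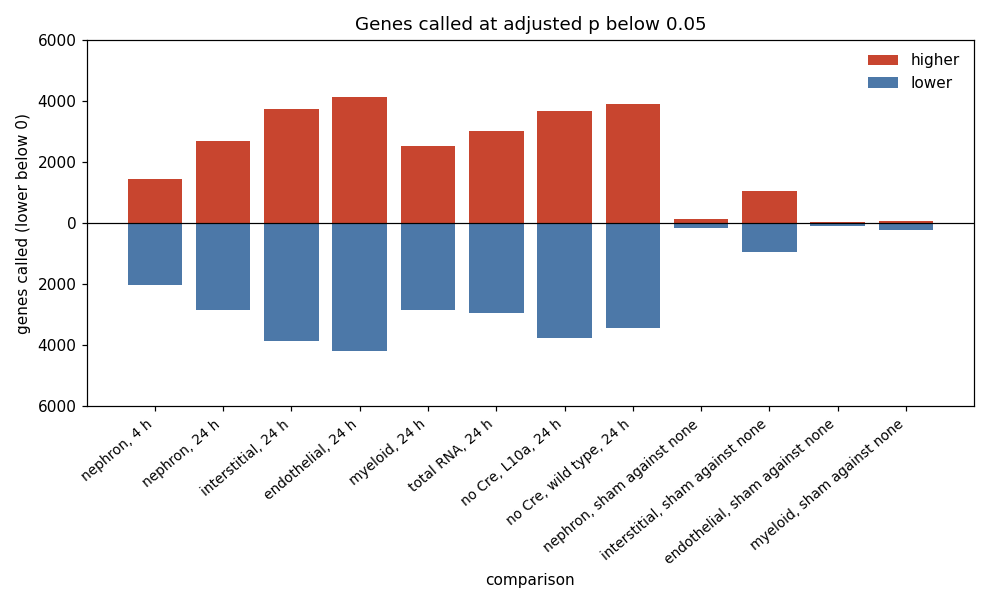
Number of genes called higher (bars above 0) and lower (bars below 0) at adjusted p below 0.05 in 12 comparisons, 8 of injured against sham and 4 of sham against no surgery. IRI at 24 h called 5378 to 8309 genes in the 4 lines, and sham surgery 142 to 1985.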

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

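The tests in this part of whether carried-over RNA, normalization, a swapped label, dilution, an earlier time point, fat or RNA preparation was behind a pattern were chosen after the result was seen.

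In groups of 4 arrays, 1 array far from the others was found for 3 of 30 combinations of gene and group (15 panel genes in 2 background groups), where chance alone gives about 1 in 20 groups. S100a8 in L10a background arrays after IRI had 1 array at a log2 intensity of 6.51 with the others at 6.71 to 6.75 (gap 0.835 of the range). Havcr1 in wild-type background arrays after IRI had 1 array at 10.9 with the others at 12.6 to 13.0 (0.834), and Atf3 in the same group 1 at 10.1 with the others at 12.0 to 12.1 (0.921). Differences between groups drew attention too: the IRI response differed for 4477 genes in the nephron line, 3064 in the interstitial, 5583 in the endothelial and 3555 in the myeloid line from the mean of the other 3, for 8975 genes among the 4 lines by the F test, and for 5335 genes between 24 h and 4 h in nephron arrays. Of 15 panel genes 9 had responses that differed among the lines, by adjusted p: Havcr1 0.00216, Sox9 0.00699, Fos 8.31e-08, Atf3 1.03e-08, Hspa1a 0.00228, Slc34a1 6.89e-06, Umod 0.0285, Lyz2 0.00148 and S100a8 0.00077. Havcr1 ranged in these responses from -0.15 ± 0.74 in endothelial to 4.55 ± 0.74 in myeloid arrays, and Atf3 from -0.36 ± 0.22 in myeloid to 2.42 ± 0.22 in nephron arrays. The myeloid Havcr1 change started from a low level (6.32 to 6.44 in sham, 10.59 to 11.32 after IRI). Nephron arrays stood higher for Havcr1 in both groups (10.47 to 10.90 in sham, 12.80 to 12.98 after IRI).

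Tubular injury genes rose in lines whose Cre was not meant for tubules. Tagged collecting duct cells cannot be excluded there, since the L10a labels name them as a background source without Cre. A candidate explanation is RNA carried over without the tag, tested with both backgrounds after IRI. For the risen genes the median of line minus wild-type background was -0.118 in interstitial (SE 0.212, 10 of 21 above), -0.652 in endothelial (SE 0.212, 4 of 16 above) and -0.871 in myeloid arrays (SE 0.269, 5 of 21 above). In nephron arrays it was 0.0917 with 13 of 20 above. Against the L10a background it was 0.472 in interstitial (SE 0.321, 13 of 21 above), -0.515 in endothelial (SE 0.348, 4 of 16 above) and -0.622 in myeloid arrays (SE 0.282, 9 of 21 above). Only genes that rose in a line entered, so these medians do not cover injury genes that did not rise there. After IRI Havcr1 was 7.4 to 7.6 in endothelial arrays, 10.9 to 13.0 in wild-type and 9.2 to 10.0 in L10a background arrays. After quantile normalization again 21, 16 and 21 of the risen genes stayed called and higher. The deposited TRAP values came from RMA with similar medians already, so this repeat could change little and does not exclude normalization. By these levels, the injury genes that rose in endothelial and myeloid arrays may reflect injured tubules as much as the tagged cells. For interstitial arrays this stays open, since the backgrounds disagree and the L10a labels name podocytes and collecting duct cells as a source. Levels compare composition, so the amount of carried-over RNA was not measured in any line, and small nucleolar RNAs were higher after IRI in the wild-type background itself (24 of 47). By level after IRI, with wild-type and L10a background in that order, Il6 in interstitial (10.86 against 8.18 and 6.78) and Clec4e in myeloid arrays (10.84 against 5.86 and 5.66) stood above both. So did Foxf1 in endothelial arrays (11.53 against 7.71 and 9.15), though in L10a arrays it was 7.09 after sham and so higher after IRI.

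In total RNA, IRI replicate 3 stood apart. Its correlation with the other two was 0.919 and 0.927 (0.986 between those), with Havcr1 at 7.73 against 12.0 and 12.6, Fgb at 6.58 against 10.5 and 10.7 and Egf at 11.2 against 7.55 and 7.52, while Krt20 was 11.2, Lcn2 11.8 and Sox9 8.80. A sham array under an IRI label was ruled out, since its change from sham followed that of the other two with a slope of 0.748 (SE 0.0177, 1072 genes). Immediate early genes were higher in replicate 3 by a median of 0.731 (SE 0.176, 16 of 20). This argues only against RNA like that of replicates 1 and 2 diluted with sham RNA. Its median intensity was also higher, which may add to that difference. Dilution of other injured RNA with sham RNA was not tested and is not excluded. A kidney nearer the 4 h state stays open. The correlation of its change with that at 4 h in nephron arrays exceeded that of the mean of the other two by 0.0109 (0.28 against 0.175 and 0.319 for the single arrays), while its correlation with the 24 h change was lower (0.448 against 0.71 and 0.86). The intensities of replicate 3 were distributed unlike those of the other total RNA arrays. The median was 53.3 against 43.9 to 45.4 there, and the mean 238 against 269 to 279. Milder injury of that animal or this unlike distribution might also remain as explanations, and neither was tested.

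Sham and unoperated interstitial arrays differed in 1985 genes, more than in the other lines in the main fit but not in every alternative (350 against 973 in nephron arrays with only the arrays compared, 3034 against 3076 in myeloid arrays with array weights). Less fat in the sham samples is a possible explanation that stays open: 10 of 18 adipocyte genes were lower, with a median of -0.97. A difference in RNA preparation may contribute, since small nucleolar RNAs were higher for 15 of 47 and the sham change correlated with the difference between IRI replicates 1 and 2 and replicate 3 across called genes (r = 0.548 over 1970 genes, 71.8 percent with the same sign). Mean small nucleolar RNA levels were 6.29, 6.43 and 6.32 in interstitial sham arrays, 5.64, 5.75 and 5.75 without surgery and 6.75, 7.03 and 6.01 after IRI.

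Regrouping the arrays asked whether chance could give as many calls. For 11 comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. In each of them only the real grouping reached its count (1 of 10), with the highest other count after it: IRI at 24 h 5503 and 2 in nephron, 7579 and 53 in interstitial, 8309 and 3 in endothelial, 5378 and 2 in myeloid arrays and 5958 and 2165 in total RNA. The same pairs for sham against no surgery were 311 and 1 in nephron, 1985 and 790 in interstitial, 142 and 11 in endothelial and 323 and 139 in myeloid arrays, and in the nephron line 3492 and 3 at 4 h and 5335 and 16 between the time points. Of 35 splits, 1 reached the 8962 genes between the backgrounds (highest other 4871). Of 100 groupings, the real one included, 1 was as large for the nephron line (highest other 8965), 2 for interstitial (6583), 1 for endothelial (6706) and 2 for myeloid (8880) without surgery. For the response differences 1 was as large in nephron (2651), 7 in interstitial (5567), 4 in endothelial (6144) and 2 in myeloid arrays (5304), and 1 for the F test (6486). Exchanging IRI and sham labels leaves the real IRI effects in the data, so the 7 groupings do not show that the interstitial count arose by chance, and chance is not excluded there by this test either. In the other regroupings real differences likewise stay in the data and widen the spread within the mixed groups. Their counts are therefore not those of data without change.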

How the results depend on the processing

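Counts of calls were compared across alternatives, many of which leave out 1 array: of 495 alternative counts 427 stayed within 1.5 times the reported count and 68 moved. The alternatives that leave out the total RNA arrays or take them as reference were added after seeing the data, and the others were planned. Named genes kept their call, and their direction where called, in 2227 of 2280 cases with quantile normalization again (43 lost and 10 gained the call). Kept cases were 2272 with an eBayes trend and 2275 with the mean of all probe sets. Without the filter on dim probe sets they were 2271, and with array weights 2208. Results called in neither fit counted as kept whatever their direction, and F test results have no direction. Reversals were counted only among results called in either fit. With only the arrays of the groups compared, 1622 of 1833 cases were kept (194 lost the call). With a 2-fold change asked besides, 1620 of 2265 were (645 lost it). With 3 arrays in most groups, precision is limited. The planned use of total RNA as the reference on the deposited scale was not run, since those arrays had lower median intensities. With that reference after quantile normalization, 103 of 477 named results of the line comparisons reversed, among those in the text Angptl7 (-1.22) and Slc22a30 (-0.57) in the nephron line, while Cox8b (1.11) and Retn (0.40) in the interstitial line lost the call.

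Asking for at least a 2-fold change besides the adjusted p lowered each count by construction. IRI at 24 h then gave 1240 genes in nephron, 1909 in interstitial, 2048 in endothelial and 1235 in myeloid arrays and 1219 in total RNA, sham against no surgery 42, 233, 18 and 112 in the 4 lines in that order, response differences 829, 557, 1198 and 584, and the lines without surgery 2746, 1226, 1816 and 1390. The counts were 414 at 4 h, 1087 from 4 h to 24 h, 1826 in L10a and 2147 in wild-type background arrays and 2503 between these. Array weights lowered the total RNA count to 4061 and raised the other counts, among them myeloid IRI to 9669, sham against no surgery to 2355, 3034, 380 and 3076, response differences to 7848, 6024, 9352 and 7985, the F test to 13830, 4 h to 6369 and 24 h against 4 h to 8033. The cause was not tested.

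With only the arrays of the groups compared, fewer arrays set the spread: total RNA gave 689 genes, sham against no surgery 973 in nephron, 350 in interstitial, 20 in endothelial and 26 in myeloid arrays, and 4 h 5557. Without the total RNA arrays sham against no surgery gave 907 in nephron, 3562 in interstitial and 681 in myeloid arrays, the interstitial response difference 4796 and 4 h 5270. Only genes above the wild-type background left fewer genes tested, with 3503 called in nephron, 4403 in interstitial and 3539 in myeloid arrays after IRI. These genes were chosen partly by their direction of change, so the counts do not compare with those over all genes. With total RNA as the reference the interstitial line differed in 9513, the endothelial in 12260 and the myeloid line in 12090 genes, and the cause was not tested. With no surgery as control 8 of the 580 named results reversed. With an estimated correlation 50 of 594 list tests passed camera, against 271 with the preset one.

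Leaving out 1 array at a time gave 105 to 220 genes for sham against no surgery in nephron, 809 to 2562 in interstitial, 55 to 177 in endothelial and 35 to 550 in myeloid arrays, and 4944 to 7585 for IRI in L10a background arrays (4944 without sham replicate 1, where the lone sham array is assumed to vary like the other groups). IRI at 24 h ranged over 4268 to 4870 in nephron, 6257 to 7142 in interstitial, 6676 to 7885 in endothelial and 4213 to 5205 in myeloid arrays and 4615 to 7682 in total RNA.

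The labels number the arrays of each group, and a replicate block was fitted as the paired alternative. It moved no count beyond 1.5 times: the IRI counts became 5757 in nephron, 7884 in interstitial, 8602 in endothelial and 5675 in myeloid arrays. The labels do not say whether the numbers pair the arrays, and with so few arrays per group the values cannot settle it. In 0 of 14 comparisons did every pair of same-numbered arrays correlate above 0.1 in their deviations from the group means (range -0.583 to 0.512). In 1, 24 h against 4 h, every array correlated best with its own number.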

Other observations

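Of the tests here only the count of small nucleolar RNAs was chosen after the result was seen. Cholesterol synthesis genes fell beyond the nephron: 8 of 14 in interstitial (9 adjusted over the list alone), 9 in endothelial (10) and 10 in wild-type background arrays (10), with adjusted p = 0.23, 0.34 and 0.13 with an estimated correlation. Targets of p53 rose in 9 of 13 in interstitial and 9 in endothelial arrays, with 1 lower in each (adjusted p = 0.18 and 0.26 with an estimated correlation), and in 5 in myeloid arrays, where Trp53inp1, which promotes autophagy and cell death, rose by 2.32 ± 0.17. Complement and coagulation genes rose in 8 of 15 in interstitial arrays with 3 lower (adjusted p = 0.43 with an estimated correlation), led by the thrombin receptor gene Thbd (3.54 ± 0.23) and Fgb (3.49 ± 0.51). In endothelial arrays Adm, which relaxes vessels, rose by 2.88 ± 0.20 among 7 of 19 hypoxia and glycolysis genes.

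Slc34a1 fell in interstitial (-0.49 ± 0.15) and myeloid arrays (-1.27 ± 0.15) after IRI, though the interstitial fall did not pass without IRI replicate 1 (-0.389, adjusted p = 0.0577), and S100a8 was higher by 2.13 ± 0.33, 2.47 ± 0.33 and 2.45 ± 0.33 in interstitial, endothelial and myeloid arrays. In myeloid arrays without ischemia, interferon response genes were lower after sham surgery in 4 of 16 (8 adjusted over the list alone, adjusted p = 0.035 with an estimated correlation). In endothelial arrays 1 of 16 collecting duct genes was higher after sham surgery (8 adjusted over the list alone, adjusted p = 0.0013 with an estimated correlation). After IRI 28 of 47 small nucleolar RNAs were lower in L10a than in wild-type background arrays. After IRI at 24 h the probe sets of Hk1 moved in opposite directions in nephron, interstitial, total RNA and both sets of background arrays, those of Top2a in myeloid and wild-type background arrays and those of Nphs1 in wild-type background arrays. At 4 h those of Cycs did so in nephron arrays (-0.193 to 0.409). Between the backgrounds after IRI, probe sets of Hk1, Top2a and Nphs1 differed in opposite directions.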
